A study of Mus musculus with 13 samples.

How the data were processed

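The 12 ChIP libraries and 1 input library of E12.5 male PGC were made from mouse cells with an EGFP tag on BLIMP1, per the labels. d2 PGCLC were sorted for KIT, d6 PGCLC for SSEA1 and integrin beta-3, E12.5 PGC for SSEA1, intestinal epithelium for GFP and EPCAM, photoreceptor precursors for GFP, and plasmablasts for GFP and CD138, per the labels. The input library was not analysed here. Per the submitters' processing notes, the tools were Trim Galore 0.3.7, cutadapt 1.7.1, Bowtie 1.1.2 and MACS2 2.1, with the mouse build mm10. The deposited lists hold, for each library separately, the chromosome and the position of each summit. They carry no height, score or p-value. The calling threshold, the control used for calling, the read depth and whether positions count from 0 or 1 were not given in the sources used here, so positions are printed as the lists give them and may be off by 1 bp. Without read depth, a library with more summits may be deeper sequenced or called at another threshold, and this applies to every number of summits, regions or genes.

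Groups were taken from the labels. The male and female E12.5 PGC libraries are separate groups with 1 library each, and were treated as the 2 libraries of one cell type where cell types were compared. Chromosomes 1 to 19, X and Y were used. Summits of any libraries at most 200 bp apart were merged into regions by single linkage (median width 0 bp, 99th percentile 381 bp, largest 1387 bp). A region was bound in a cell type when both of its libraries had a summit in it, and restricted when no library of another cell type had one. Chance levels came from shifting lists by 20 kb in each direction, and for regions in all cell types by a different multiple of 60 kb for each library. Identical summit positions between libraries numbered at most 244, between the plasmablast replicates, so no library was a copy of another.

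Genes came from a table of the GRCm38.p6 assembly, which has the coordinates of mm10, with 21887 protein-coding genes and 49943 genes of all kinds. It gives no strand, exons or sequence. The test design had named transcription start sites. In their place a summit was near a gene when within 1 kb of either end of a protein-coding gene, and a gene was bound in a cell type when both libraries had such a summit. A list value near a gene end can therefore concern the 3' end. The summits of the 2 libraries need not lie in the same region or at the same end, so a bound gene may have no bound region. Of genes longer than 5 kb, 7192 were bound at 1 end and 328 at both in plasmablasts, and 1556 and 21 in d2 PGCLC. Exon or intron positions, motif searches and a covariate for CpG content need a genome sequence or transcript models and were not run here.

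The 21 gene lists were fixed before the data were examined. Every member was matched by symbol or older symbol except Mx1 and Mx2, which the table holds as pseudogenes, so 48 interferon genes were used. List genes were compared with all other protein-coding genes by Fisher's exact test, two-sided, for 21 lists and 6 cell types, with Benjamini-Hochberg adjustment over the 126 tests. Odds ratios, where given, are log2 values with 0.5 added to each cell. Genes are the units of these tests, so the p-values describe lists within these libraries, not animals. The planned comparison of 2 cell types needed a ranking by peak score. In its place, chosen after seeing the files, the genes bound in exactly 1 of the 2 cell types were split into list genes and others and tested by Fisher's exact test, with adjustment over 315 tests. The plan had set an equal number of genes per cell type, which this replacement does not do.

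Named genes followed a rule fixed before the data were examined, with the ranking by score replaced by the number of bound regions within 5 kb of either gene end, then the distance between the libraries' nearest summits, then the symbol. The rule takes, per cell type, the 10 highest-ranked bound genes, the 5 highest-ranked with no summit within 5 kb in another cell type, and up to 4 members per list, the 10 highest-ranked bound in all 6 cell types, and 15 fixed genes with their state in every library. Not all were printed, and the results of some single genes are not reported here.

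Replicate overlap was tested by an exact permutation test over all pairings of 10 libraries, one-sided, and the relation between cell number and summits by 100000 permutations. Shares have Clopper-Pearson 95% intervals, which cover counting error only. The list test was tested on simulated data, with the 21887 genes bound at each cell type's own rate and 200 lists of 30 genes per case. Lists with 4 times the odds gave p under 0.05 in 85.5% of draws in d2 PGCLC, 85.5% in d6 PGCLC, 75.5% in E12.5 PGC, 76.0% in intestinal epithelium, 90.0% in photoreceptor precursors and 95.0% in plasmablasts. Lists with no effect did so in 1.0% to 4.0%. These simulated p-values were unadjusted and genes were bound independently, whereas the calls use adjusted p, which is harder to pass. The rates therefore do not give the power of the calls, nor cover genes that share regions. Alternatives covered the merging distance, binding in either library, each replicate left out with the other library alone defining its cell type, the window at gene ends, the genes used, and thinned lists. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.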

Results

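BLIMP1, encoded by Prdm1, is a zinc-finger transcriptional regulator that acts in primordial germ cell (PGC) specification, in the fetal intestine, in the retina and in antibody-secreting cells. Its binding was mapped by ChIP-seq with an antibody to GFP in mouse cells carrying an EGFP-BLIMP1 knock-in. The 12 ChIP libraries came from 6 cell types. Day 2 and day 6 PGC-like cells (d2 and d6 PGCLC), which are germ cell precursors made in culture from embryonic stem cells, had 2 replicates each. PGC of the embryo at E12.5 (E, embryonic day) had 1 male and 1 female library. Embryonic intestinal epithelium (E16.5), retinal photoreceptor precursors (postnatal day 4) and plasmablasts (B cells stimulated for 3 days) had 2 replicates each. The question was where one regulator binds in cells of different fates. Positions are those of mm10.

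The libraries differed in the number of summits, the single positions at which peaks were called. The median library listed 15822.5 summits on chromosomes 1 to 19, X and Y. The 2 intestinal libraries listed 7998 and 12115, the photoreceptor precursor libraries 10861 and 13955, and the plasmablast libraries 40750 and 45122. The d2 PGCLC libraries listed 16234 and 26657 summits, and the E12.5 PGC libraries 12291 (male) and 17798 (female). The d6 PGCLC replicates stood apart from each other, with 76185 summits in replicate 1 and 15411 in replicate 2. The number of cells in a ChIP ran from 3.0 to 30 in units of 1e5 and showed no correlation with the number of summits over the 12 libraries (Pearson r = -0.05, permutation p = 0.857; Spearman rho = 0.07, permutation p = 0.829; both two-sided, adjusted p = 0.857 for each of the 2 measures). Without the 2 libraries farthest from the median cell number r was -0.26 (permutation p = 0.525, n = 10), and without d6 PGCLC replicate 1 it was 0.30 (permutation p = 0.330). Read depth was not given in the sources used here, so summit numbers carry no depth correction.

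**Figure D1:**
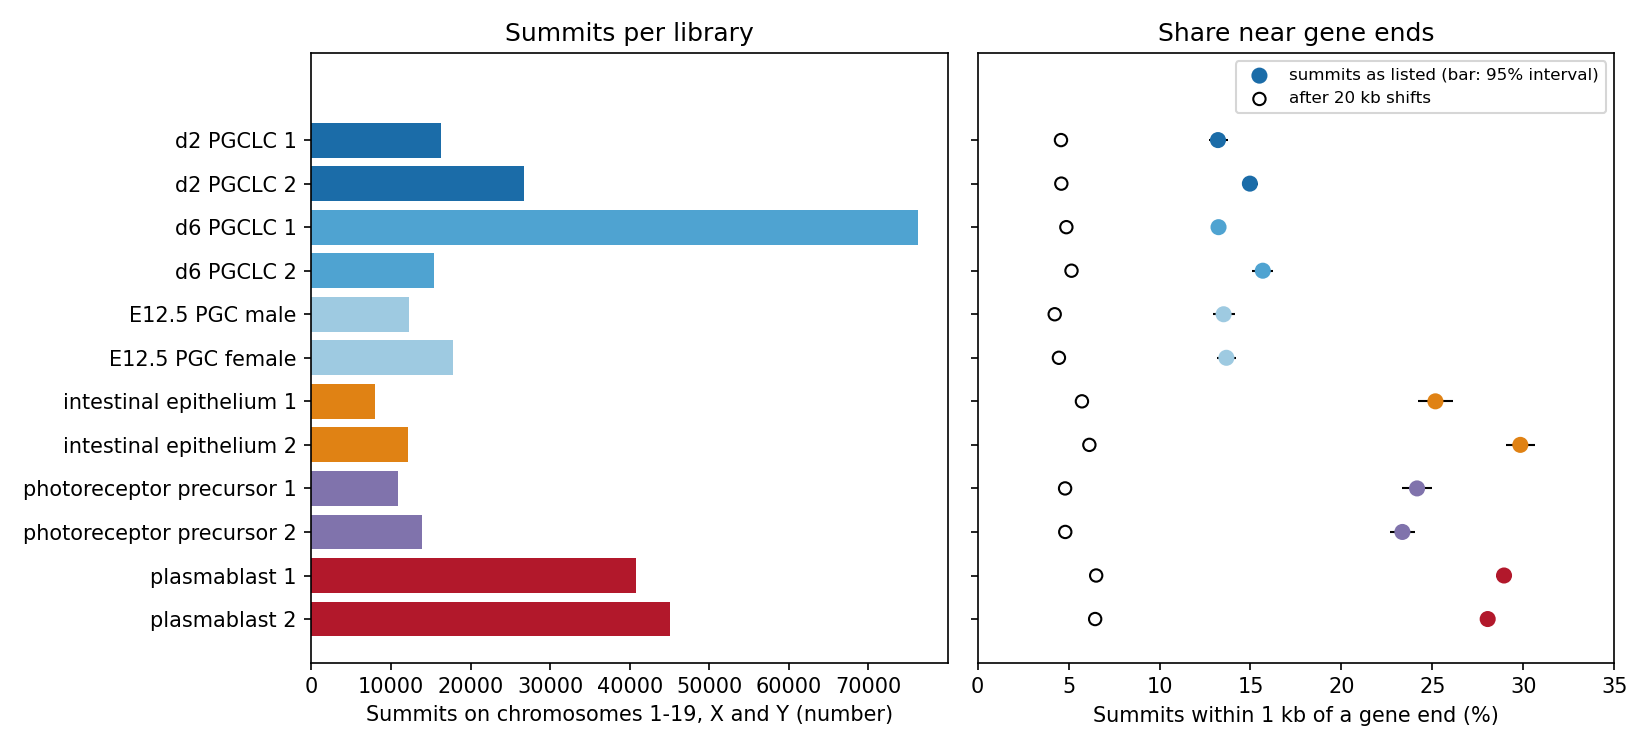
Summits per library on chromosomes 1 to 19, X and Y (left, number; bars start at 0) and share of these summits within 1 kb of an end of a protein-coding gene (right, %; filled points with 95% Clopper-Pearson intervals, open points after 20 kb shifts) in the 12 libraries. The 6 germ-lineage libraries lie between 13.2% and 15.7%, the 6 somatic libraries between 23.4% and 29.8%.

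Replicates of a cell type had on average more summits in common than other pairings of the libraries. Photoreceptor precursor replicates shared 70.3% of the shorter list within 200 bp, d2 PGCLC replicates 69.9%, d6 PGCLC replicates 70.0%, intestinal replicates 58.6% and plasmablast replicates 55.0%. The male and female E12.5 PGC libraries shared 59.7%. After a 20 kb shift of one list, between 0.294% and 3.10% was shared over all 66 pairs of libraries. The mean Jaccard index of the 5 replicate pairs was 0.319, against a median of 0.120 over all ways to pair the 10 libraries (exact permutation test, one-sided, p = 0.0021). The d6 PGCLC replicates, with lists of unequal length, had the lowest index of these pairs, 0.133. For d6 PGCLC replicate 2 the index was higher with the d2 PGCLC replicates (0.360 and 0.286) and the male and female E12.5 PGC libraries (0.267 and 0.307). With replicate 1 libraries paired with replicate 2 libraries only, as a replicate block, the same mean of 0.319 gave p = 0.0167 over 120 pairings (exact permutation test, one-sided). The labels do not say whether replicates came from separate cultures or animals, so the p-values measure the spread between these libraries.

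Germ-lineage libraries also shared many summits across stages. Any pair of the 6 PGCLC and PGC libraries shared between 47.5% and 70.6% of the shorter list. A germ-lineage and a somatic library shared between 18.8% and 48.7%, and somatic libraries of different cell types between 23.1% and 42.1%. Intestinal epithelium shared 39.0% to 42.1% with plasmablasts and 23.1% to 28.4% with photoreceptor precursors, but by the Jaccard index the order was turned (0.0653 to 0.0999 and 0.115 to 0.125). Lists of greater length contain more of a shorter list, and the 48.7% belongs to d6 PGCLC replicate 1.

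**Figure D2:**
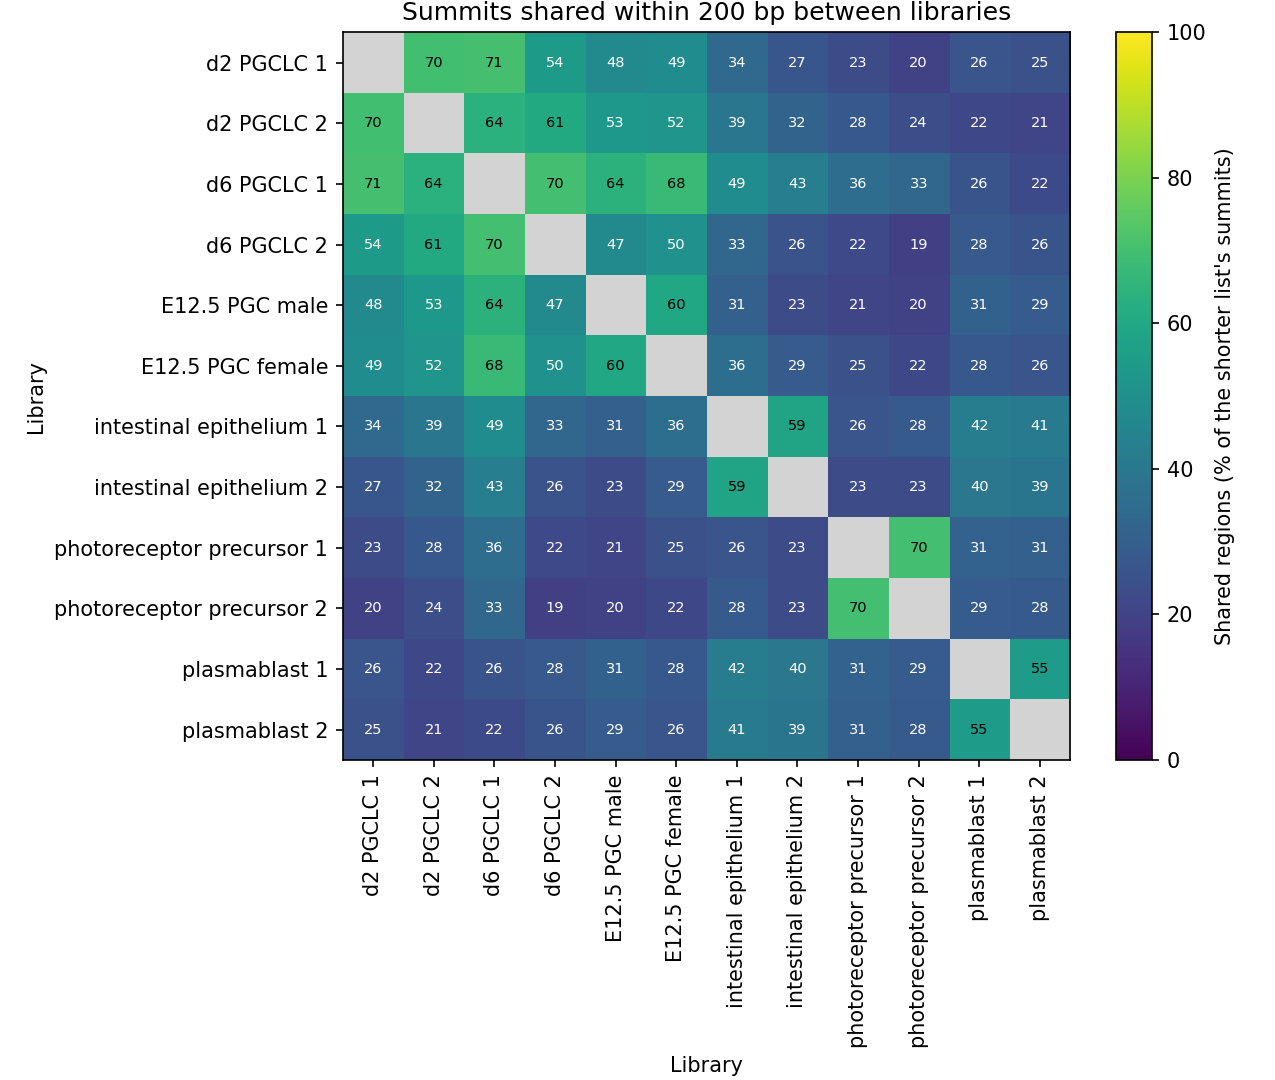
Share of the shorter list's summits found within 200 bp in the other library (%, colour and numbers) for each pair of the 12 libraries, named on both axes. Values within the germ lineage run from 47.5% to 70.6% and those between germ-lineage and somatic libraries from 18.8% to 48.7%.

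Merging the summits of all libraries gave 155003 regions, of which 41901 were bound, meaning found in both libraries, in at least 1 cell type. Plasmablasts had 23218 bound regions, d2 PGCLC 11947, d6 PGCLC 11379, photoreceptor precursors 7868, E12.5 PGC 7666 and intestinal epithelium 4956, with a median of 9623.5. A total of 1093 regions were bound in all 6 cell types, and 0 after the lists were shifted against each other. Regions bound in 1 cell type with no summit in any library of another numbered 18014 in all. They made up 51.8% of the plasmablast regions (12035) and 43.5% of the photoreceptor precursor regions (3422), but 18.6% in intestinal epithelium (923), 7.08% in d6 PGCLC (806), 5.06% in d2 PGCLC (605) and 2.91% in E12.5 PGC (223). These counts carry no correction for list length. Random thinning of each list to the shortest, chosen after seeing the data, lowers the counts of long lists most by its construction and turned the order of bound regions, to 3285.7 in photoreceptor precursors, 3211.6 in intestinal epithelium, 2216.1 in E12.5 PGC, 1735.3 in d2 PGCLC, 805.6 in plasmablasts and 607.5 in d6 PGCLC (means of 20 draws). Of these thinned regions, 1833 were restricted in photoreceptor precursors, 1055.5 in intestinal epithelium, 444.4 in E12.5 PGC, 473.9 in d2 PGCLC, 527.7 in plasmablasts and 134.5 in d6 PGCLC. Regions bound in all 6 cell types numbered 2150 with binding in either library and 0.1 with thinned lists. With 1 replicate left out, and the other alone defining the cell type, bound regions (pairs of values: without replicate 1, then without replicate 2) rose to 26472 in d2 PGCLC (without replicate 1), 75891 in d6 PGCLC (without replicate 2), 17658 or 12179 in E12.5 PGC (without the male or the female library), 11988 or 7927 in intestinal epithelium, 13836 in photoreceptor precursors (without replicate 1) and 44993 or 40596 in plasmablasts. Restricted regions rose, in the same order, to 6068 or 2431 in d2 PGCLC, 2676 or 44822 in d6 PGCLC, 3145 or 2622 in E12.5 PGC, 3910 or 2429 in intestinal epithelium, 6741 in photoreceptor precursors (without replicate 1) and 30353 or 25489 in plasmablasts. Without d6 PGCLC replicate 1 those of d2 PGCLC numbered 1894 and those of E12.5 PGC 613, and without d2 PGCLC replicate 2 those of d6 PGCLC numbered 1313. In all, restricted regions numbered 62248 without d6 PGCLC replicate 2 and 36534 or 31655 without plasmablast replicate 1 or 2.

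The 3 germ-lineage cell types had 1624 regions in common that held no summit in any somatic library. This was the largest of the 20 choices of 3 cell types against the other 3. The next, d2 PGCLC with d6 PGCLC and plasmablasts, had 89 regions, and the 3 somatic cell types against the germ lineage had 15. With E12.5 PGC defined by the female library alone the germ-lineage count was 2481, with binding in either library 4943, and with thinned lists 4.9. A rank of 1 in 20 is the smallest this design can give.

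Across the germ-lineage stages, 4683 regions were bound at d2, at d6 and at E12.5, and 65.3% of these also held a somatic summit. With binding in either library 10873 regions were bound at all 3 stages, and with thinned lists 11.5. The Jaccard index of bound regions was 0.485 between d2 and d6 PGCLC, 0.399 between d6 PGCLC and E12.5 PGC, and 0.371 between d2 PGCLC and E12.5 PGC. Of the E12.5 regions 70.9% were bound at d6 and 69.2% at d2. Regions bound at 1 stage with no summit at the other 2 stages numbered 761 at d2, 1127 at d6 and 347 at E12.5. Between neighbouring stages, 1245 regions were bound at d2 and d6 without an E12.5 summit, 242 at d6 and E12.5 without a d2 summit, and 31 at d2 and E12.5 without a d6 summit. The length of d6 PGCLC replicate 1 enters these numbers, since any of its summits counts as a d6 summit.

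The male and female E12.5 PGC libraries, 1 per sex and therefore without a test, had 7666 regions in common. A further 4502 were found in the male library alone and 9980 in the female library alone. PGCLC libraries held a summit in 95.5% of the common regions, 40.2% of the male-only and 65.5% of the female-only regions. X-chromosomal summits made up 2.41% of the female list (429 summits, Clopper-Pearson 95% interval 2.19% to 2.65%) and 1.42% of the male list (174 summits, 1.21% to 1.64%). Of the common regions 1.71% (131) lay on X, of the male-only 0.955% (43) and of the female-only 2.98% (297). In the other 10 libraries the X share lay between 1.04% and 2.16%.

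Each somatic library had a larger share of its BLIMP1 summits at the ends of genes than each germ-lineage library. The share of summits within 1 kb of either end of a protein-coding gene was 28.5% ± 0.635 in plasmablasts, 27.5% ± 3.30 in intestinal epithelium and 23.8% ± 0.570 in photoreceptor precursors (mean ± SD of 2 libraries each). It was 14.1% ± 1.24 in d2 PGCLC, 14.5% ± 1.72 in d6 PGCLC and 13.6% ± 0.109 in E12.5 PGC. Shifted by 20 kb, the lists gave 4.23% to 6.52%, and the median library 19.5% as listed. The mean of the 3 somatic cell types exceeded that of the 3 germ-lineage types by 12.53 percentage points (26.6% ± 2.50 against 14.1% ± 0.432, SD over cell types, n = 3 each; exact permutation test, two-sided, p = 0.10, the smallest this design allows). The annotation used here carries no strand, so either end of a gene may hold its transcription start. Summits inside genes but away from their ends made up 45.1% to 54.5% of every list.

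Of the 1093 regions bound in all 6 cell types 33.9% lay near a gene end (95% interval 31.0% to 36.7%), against 15.1% of the regions bound in 3 (13.9% to 16.4%) and 21.9% of those bound in 1 (21.4% to 22.4%). The share was 20.8% for regions bound in 2, 20.8% in 4 and 28.6% in 5. These values pool cell types whose own bound regions had shares from 13.5% (d2 PGCLC) to 31.6% (plasmablasts). Among regions restricted to 1 cell type the share was 6.11% in photoreceptor precursors, 9.21% in intestinal epithelium, 4.04% in E12.5 PGC, 5.79% in d2 PGCLC and 9.68% in d6 PGCLC, but 24.0% in plasmablasts.

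At the level of genes, 9712 of 21887 protein-coding genes were bound within 1 kb of an end in at least 1 cell type, and 498 in all 6. Plasmablasts had 8691 such genes (39.7% of all), d6 PGCLC 2128, photoreceptor precursors 2118, d2 PGCLC 1840, intestinal epithelium 1596 and E12.5 PGC 1267, with a median of 1979. Without 1 replicate the number was 7866 in d6 PGCLC (replicate 2 left out), 3739 in d2 PGCLC (replicate 1), 3686 in intestinal epithelium (replicate 1), 3183 in photoreceptor precursors (replicate 1) and 2474 in E12.5 PGC (the male library). With thinned lists the order turned here too, with 1139.3 in intestinal epithelium, 1019.9 in photoreceptor precursors, 611.8 in plasmablasts, 423.9 in E12.5 PGC, 348.4 in d2 PGCLC and 190.3 in d6 PGCLC. Genes bound in all 6 cell types with the most regions around them included Nfix (chromosome 8, 84704712 to 84801238), Trib3 (chromosome 2, 152337425 to 152344060), B4galt3, Pou3f3, Cox17, Igf1r, Zbtb18, Bcl9l, Fbxl14 and Plgrkt. Nfix and Trib3, a transcription factor and a stress-induced pseudokinase, each had 21 bound regions within 5 kb of their ends, summed over the 6 cell types. At Nfix, the 2 nearest summits in d6 PGCLC lay at opposite ends of the gene. The same held for B4galt3 in d2 PGCLC, where the nearest summits of the 2 libraries lay 6010 bp apart. A total of 42 genes were bound in the 3 germ-lineage types and in no somatic library, and 10 in the 3 somatic types and in no germ-lineage library.

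Myc, the proto-oncogene driving cell growth, was bound in all 12 libraries. Every library had a summit between 197 and 271 bp from the lower-coordinate end of Myc (chromosome 15, 61985341 to 61990361). These summits spanned 61985070 to 61985551 and lay on both sides of that end, so the 12 libraries need not share 1 site. Prdm1 itself (chromosome 10, 44437174 to 44528558) had a summit within 5 kb of an end in all 12 libraries, and was bound within 1 kb in intestinal epithelium and plasmablasts. In intestinal epithelium the summits of the 2 libraries lay in different regions, so no bound region lay within 1 kb of its ends. The nearest summits to Prdm1 in d2 PGCLC lay at 1011 and 1012 bp and in d6 PGCLC at 1025 and 1014 bp, just outside that window. Socs1, an inhibitor of cytokine signalling, was bound in all cell types but intestinal epithelium, in 10 libraries.

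Genes of MHC class I and antigen processing were bound in every cell type. Of the 20 genes in this list, which load peptides and present them to T cells, 15 were bound in d2 PGCLC, 15 in d6 PGCLC, 11 in E12.5 PGC, 12 in intestinal epithelium, 11 in photoreceptor precursors and 20 in plasmablasts. The corresponding shares of all other genes were 8.35%, 9.66%, 5.74%, 7.24%, 9.64% and 39.7% (Fisher's exact test, two-sided, highest adjusted p = 4.49e-06 over the 6 cell types). Tap1, a subunit of the peptide transporter (chromosome 17, 34187556 to 34197225), and its neighbour Psmb9, an immunoproteasome subunit (34182030 to 34187330), were bound in all 12 libraries. Psmb8 (34198195 to 34201454) was bound in d2 and d6 PGCLC, photoreceptor precursors and plasmablasts. B2m, the light chain of class I molecules, was bound in plasmablasts alone, and no other library had a summit within 5 kb of it. Several of these genes lie side by side and the H2 genes are near-identical copies, among which short reads are hard to place. The 15 genes of d2 PGCLC had 14 bound regions near their ends. With 1 gene counted per region, 14, 14, 10, 11, 10 and 19 genes were left in the 6 cell types, in the order above. Each of the 6 adjusted p stayed under 0.05 (Fisher's exact test). Only genes sharing a bound region are dropped by this count, so it removed few genes and could hardly change the calls.

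**Figure D3:**
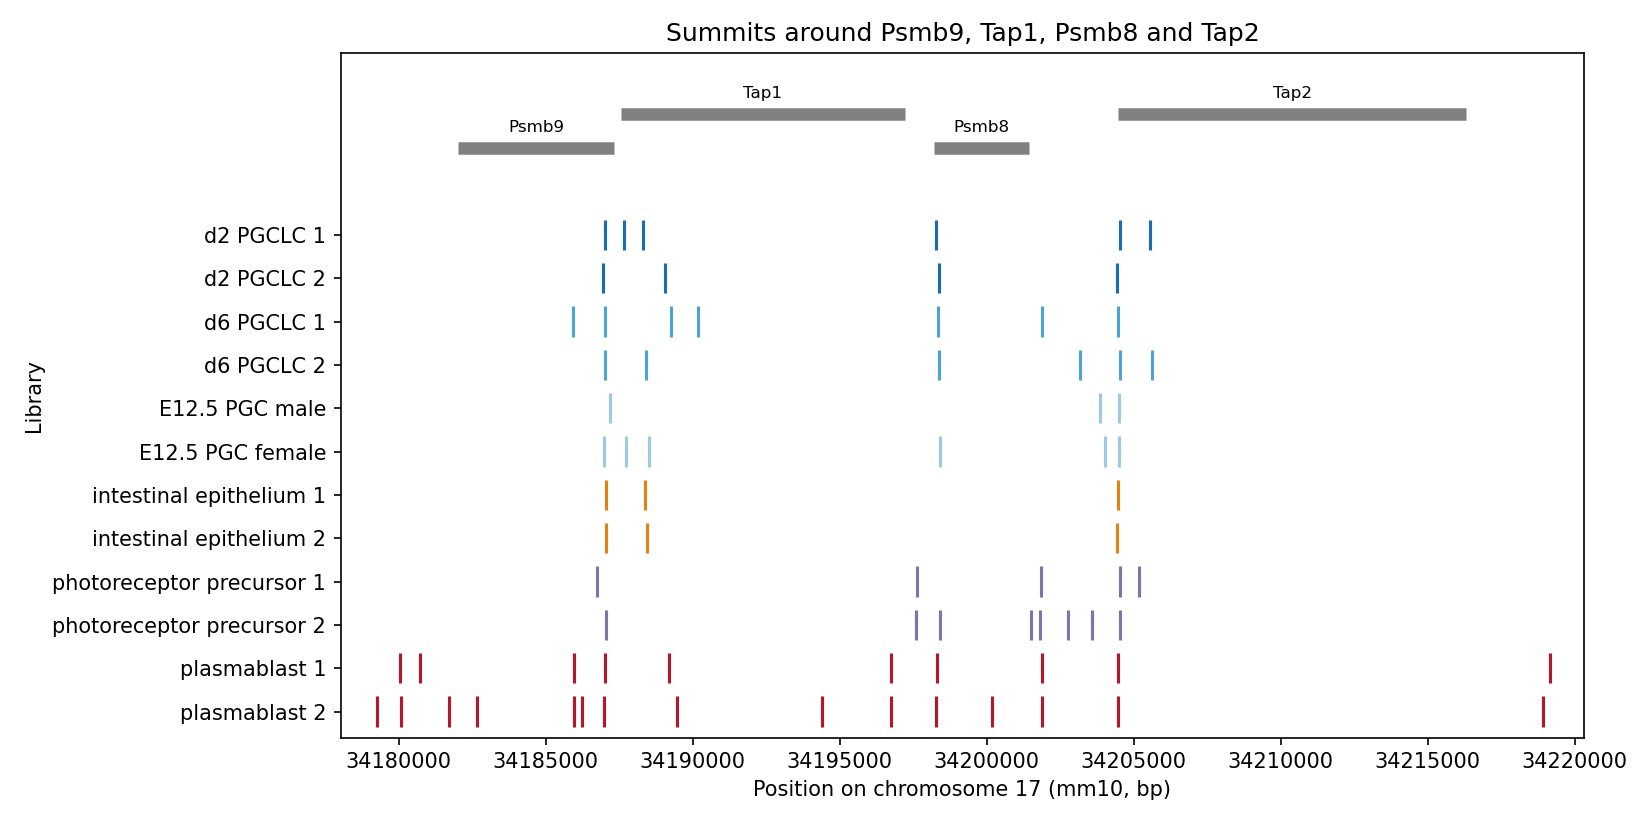
Positions of summits (vertical ticks, 1 row per library) on chromosome 17 from 34178030 to 34220321 (mm10, bp), with the genes Psmb9, Tap1, Psmb8 and Tap2 as grey bars. The 12 libraries each have a summit at the adjoining ends of Psmb9 and Tap1, and plasmablast replicate 2 has the most summits in the window, 15.

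Interferon response genes were bound above the rate of other genes in 5 cell types. Of 48 genes, 35 were bound in plasmablasts (adjusted p = 3.60e-05), 15 in d6 PGCLC (adjusted p = 0.000214), 10 in E12.5 PGC (adjusted p = 0.00194), 11 in d2 PGCLC (adjusted p = 0.00794) and 9 in intestinal epithelium (adjusted p = 0.0265, all by Fisher's exact test). In photoreceptor precursors 7 were bound, which did not pass the test. Those counts were 72.9%, 31.25%, 20.8%, 22.9% and 18.8% of the list in plasmablasts, d6 PGCLC, E12.5 PGC, d2 PGCLC and intestinal epithelium. Ribosomal protein genes, a reference list, had 91.3%, 13.0%, 13.0%, 17.4% and 17.4% bound in the same order. Gbp2, an interferon-induced GTPase, was bound in all 6 cell types. Irf1, an interferon-induced transcription factor (chromosome 11, 53770014 to 53778374), was bound in plasmablasts only, at 75 and 38 bp. The intestinal call was lost with either intestinal replicate left out (adjusted p = 0.184 without replicate 1 and 0.123 without replicate 2) and with binding in either library (adjusted p = 0.321, Fisher's exact test), and the calls in d2 PGCLC and intestine with a 5 kb window (adjusted p = 0.119 and 0.0627).

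Cell cycle genes were bound in 28 of 30 cases in plasmablasts (adjusted p = 1.20e-08), in 8 each in intestinal epithelium, d6 PGCLC and photoreceptor precursors (adjusted p = 0.00522, 0.0250 and 0.0250), and in 7 in d2 PGCLC (adjusted p = 0.0363, Fisher's exact test). In E12.5 PGC 5 were bound, short of the threshold. Myc and Ccna2, a cyclin of S phase, were among those bound in d2 PGCLC, d6 PGCLC and E12.5 PGC. Ribosomal protein genes, a reference list of genes active in every cell, were bound in 42 of 46 cases in plasmablasts (adjusted p = 5.57e-12) and 14 in photoreceptor precursors (adjusted p = 0.000462, Fisher's exact test). With a 500 bp window the cell cycle calls were lost in d2 PGCLC, d6 PGCLC, intestine and photoreceptor precursors (adjusted p = 0.502, 0.905, 0.0635 and 0.596), and the d2 PGCLC call also without either of its replicates (adjusted p = 0.199 and 0.0658) and with binding in either library (adjusted p = 0.197, Fisher's exact test).

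**Figure D4:**
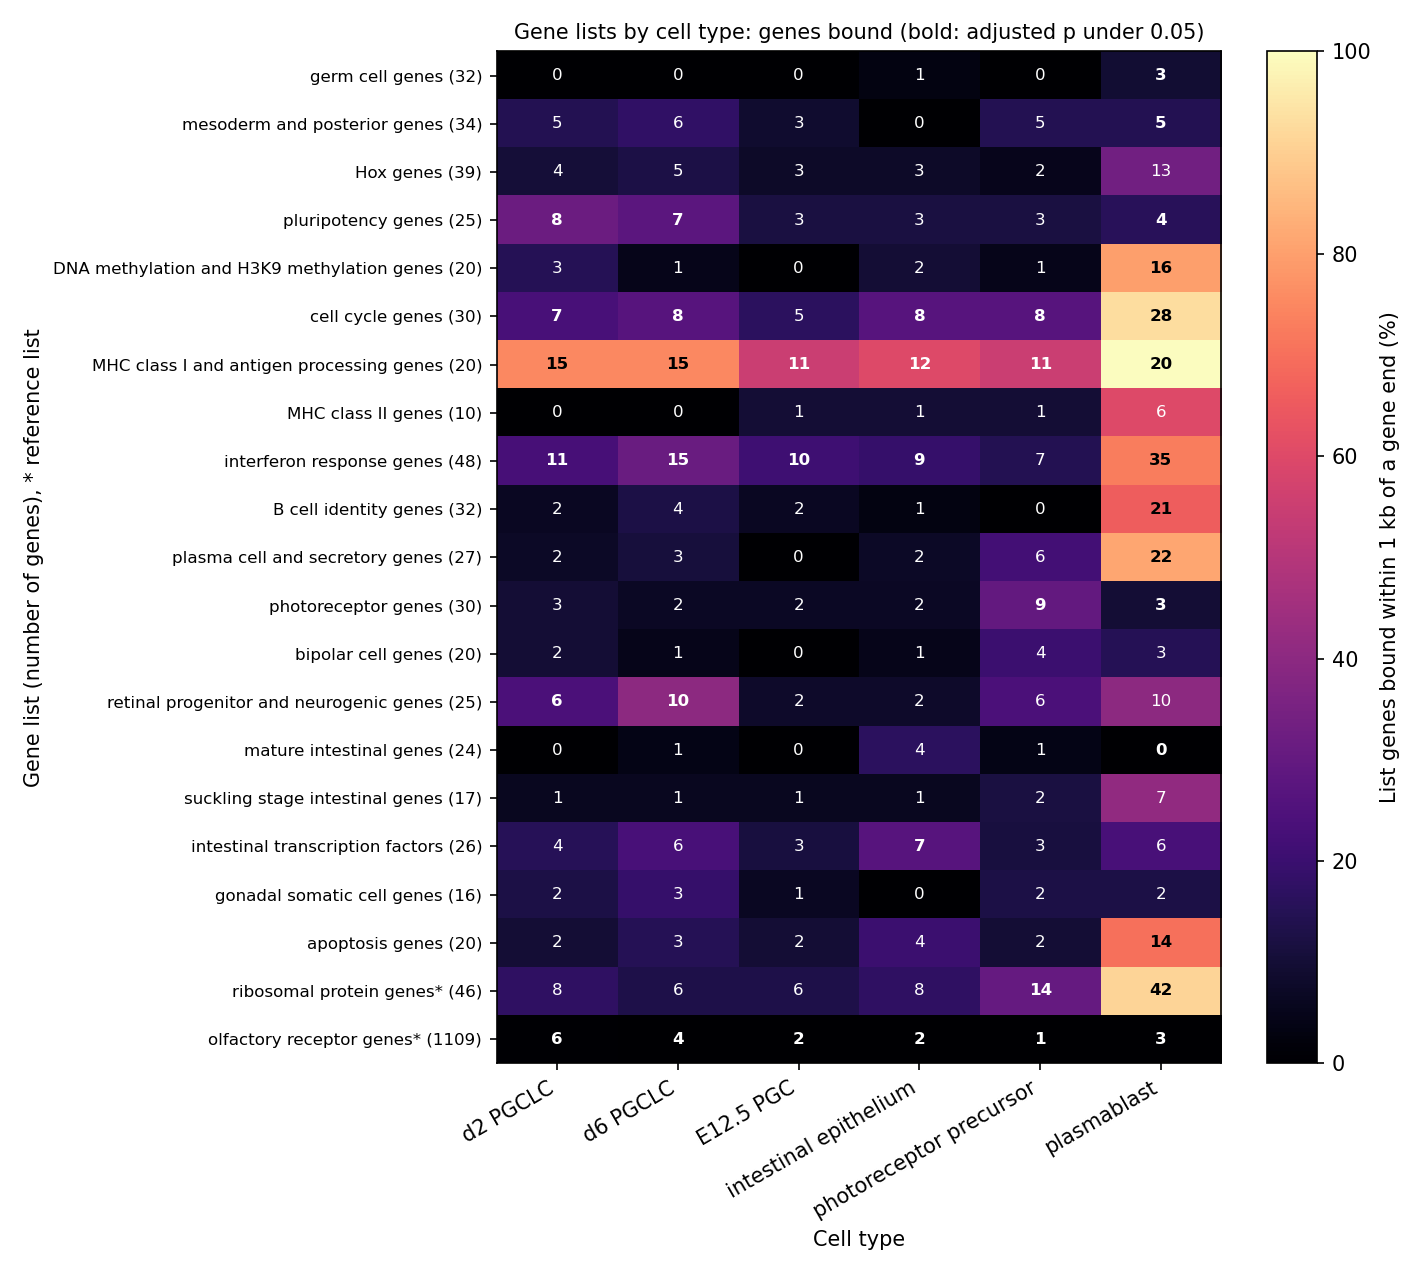
Number of genes bound within 1 kb of a gene end (numbers in cells) and share of the list (colour, %) for 21 gene lists (rows, with list size) in the 6 cell types (columns), bold where the adjusted p of Fisher's exact test was under 0.05. MHC class I genes are bound in 11 to 20 of 20 cases, olfactory receptor genes in 1 to 6 of 1109.

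In photoreceptor precursors, 9 of 30 photoreceptor genes (30.0%) were bound, against 9.65% of other genes (adjusted p = 0.00742, Fisher's exact test). The ribosomal reference list was bound at a similar rate in these cells, 14 of 46 (30.4%), so an excess of this size was not particular to photoreceptor genes. The bound photoreceptor genes included Crx, a transcription factor of photoreceptors, Neurod1, Prph2, a protein of the outer segment disc rim, and Pde6b, a subunit of the rod phosphodiesterase. At Prph2 (chromosome 17, 46910478 to 46924933) the 2 replicates had summits at 46910396 and 46910397, and at Neurod1 (chromosome 2, 79452637 to 79456636) at 79456965 and 79456966. Neither gene had a summit within 5 kb in any other cell type, and the same held for Samd7, Grk1 and Mak. Of 20 bipolar cell genes, 4 were bound, Grm6, Irx6, Bhlhe22 and Cabp5, and of 25 retinal progenitor genes 6, neither past the threshold. Compared with plasmablasts over the genes bound in exactly 1 of the 2 cell types, photoreceptor genes were bound in photoreceptor precursors in 7 cases and in plasmablasts in 1, against 356 and 6935 other genes (adjusted p = 1.72e-06, Fisher's exact test). The bipolar genes gave 3 against 2 (adjusted p = 0.0446), a call lost without photoreceptor precursor replicate 2 (adjusted p = 0.0909, Fisher's exact test).

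In intestinal epithelium, 7 of 26 intestinal transcription factors were bound (adjusted p = 0.00901, Fisher's exact test), among them Klf5, Gata6 and Nr5a2. The call was lost without intestinal replicate 1 (adjusted p = 0.164) and with binding in either library (adjusted p = 0.150, Fisher's exact test). Mature intestinal genes were bound in 4 of 24 cases, Aqp8, Vil1, Sis and Alpi, which did not pass the test in this cell type. Vil1, a structural protein of the brush border (chromosome 1, 74409384 to 74435560), had summits at 14 and 32 bp from its end in the 2 replicates and none within 5 kb in another cell type, and the same held for Nr5a2. Against plasmablasts, mature intestinal genes gave 4 to 0 (adjusted p = 7.18e-05) and intestinal transcription factors 4 to 3 (adjusted p = 0.00118, Fisher's exact test), with 192 and 7291 or 7288 other genes. Suckling stage intestinal genes were bound in 1 of 17 cases in the intestine.

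In PGCLC, pluripotency genes were bound in 8 of 25 cases at d2 (adjusted p = 0.00364) and 7 at d6 (adjusted p = 0.0292, Fisher's exact test), and in 3 in E12.5 PGC, which did not pass. Sall1, Otx2, Zic2 and Dppa5a were bound at d2, and Sall1, Tfcp2l1, Sox2 and Klf5 at d6. Retinal progenitor and neurogenic genes, which include the Notch pathway, were bound in 10 of 25 cases at d6 (adjusted p = 0.000406) and 6 at d2 (adjusted p = 0.0497, Fisher's exact test). Hes1, Dll1, Notch1 and Id1 were among those at d2 and Fgf15, Six3 and Dll1 among those at d6. Photoreceptor precursors also had 6 of 25 of this list bound, short of the threshold (adjusted p = 0.0847, Fisher's exact test). Other genes were bound at 9.66% there and at 8.39% in d2 PGCLC. Neither PGCLC stage differed from photoreceptor precursors past the threshold for this list. At d6 the 10 neurogenic genes had 7 bound regions near their ends and the 7 pluripotency genes 5, so some had none. Against plasmablasts, pluripotency genes gave 6 to 2 at d2 (adjusted p = 8.46e-05) and 4 to 1 at d6 (adjusted p = 0.00493, Fisher's exact test). The retinal progenitor and neurogenic genes gave 5 to 5 at d6, beside 502 and 7065 other genes (adjusted p = 0.0112), a call lost without d6 PGCLC replicate 2 or plasmablast replicate 2 (adjusted p = 0.106 and 0.0672, Fisher's exact test). With a 500 bp window the pluripotency calls at d2 and d6 (adjusted p = 0.143 and 0.0571) and the neurogenic call at d6 (adjusted p = 0.184) were lost, as were the differences from plasmablasts of the pluripotency genes at d2 and the neurogenic genes at d6 (adjusted p = 0.0504 and 0.172, Fisher's exact test).

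Germ cell genes were bound in 0 of 32 cases in d2 PGCLC, d6 PGCLC, E12.5 PGC and photoreceptor precursors, which did not pass the test (adjusted p = 0.247, 0.167, 0.488 and 0.167, Fisher's exact test). Prdm1, a member of this list, had its nearest summits 1011 to 1025 bp from an end in the 4 PGCLC libraries, just outside the window. Tfap2c, a partner factor of PGC specification, had a summit within 1 kb in 3 germ-lineage libraries, and in both libraries of no cell type. Mesoderm and posterior genes were bound in 5 of 34 cases in d2 PGCLC, including Sp5, Rspo3, Fgf17 and Tbx6, and 6 in d6 PGCLC, and Hox genes in 4 and 5 of 39, none past the threshold. The 5 Hox genes of d6 PGCLC had 1 bound region near their ends, so most were called from replicate summits in different regions. Hoxb1 had a summit within 1 kb in d2 PGCLC replicate 2 alone, and Klf4 was bound in plasmablasts alone. Dnmt3b, a de novo DNA methyltransferase, was bound in d2 PGCLC, d6 PGCLC and plasmablasts, and Uhrf1, a factor for maintaining DNA methylation, in d2 PGCLC, intestinal epithelium and plasmablasts. Of the 20 DNA and H3K9 methylation genes 3 were bound in d2 PGCLC, 1 in d6 PGCLC and 0 in E12.5 PGC. Gonadal somatic cell genes, which mark the cells around PGC in the gonad, were bound in 1 of 16 cases in E12.5 PGC.

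In plasmablasts, plasma cell and secretory genes were bound in 22 of 27 cases (adjusted p = 9.04e-05) and B cell identity genes in 21 of 32 (adjusted p = 0.0141), against 39.7% of other genes (Fisher's exact test). These were 81.5% and 65.6% of the lists. The ribosomal reference list had 91.3% bound in these cells, so an excess of this size was not particular to plasma cell or B cell genes. Irf4, a transcription factor of plasma cell differentiation (chromosome 13, 30749233 to 30766981), had summits at 33 and 2 bp from its end and none within 5 kb in any other cell type, and the same held for Il21r, Snn, Fam111a and Txndc11. Bcl6, a transcriptional repressor expressed in germinal centre B cells, was bound in plasmablasts and intestinal epithelium, Id3 in plasmablasts and d6 PGCLC, and Spib in plasmablasts. No bound region lay within 1 kb of the ends of Bcl6 in intestinal epithelium, since the summits of the 2 libraries lay in different regions. Pax5 had a summit 210 bp from its end in plasmablast replicate 1 and 1314 bp in replicate 2, so it was not counted as bound. Ciita, the activator of MHC class II genes, had its nearest plasmablast summits at 3963 and 3958 bp, and MHC class II genes were bound in 6 of 10 cases, which did not pass the test. DNA and H3K9 methylation genes (16 of 20, adjusted p = 0.00186) and apoptosis genes (14 of 20, adjusted p = 0.0345) were bound above the rate of other genes (Fisher's exact test), as was the ribosomal reference list. Germ cell genes (3 of 32, adjusted p = 0.00124), mature intestinal genes (0 of 24, adjusted p = 5.58e-05), photoreceptor genes (3 of 30, adjusted p = 0.00284), mesoderm genes (5 of 34, adjusted p = 0.0102) and pluripotency genes (4 of 25, adjusted p = 0.0468) were bound below it (Fisher's exact test). With a 500 bp window the calls for B cell and pluripotency genes were lost (adjusted p = 0.864 and 0.115), with a 5 kb window that for photoreceptor genes (adjusted p = 0.268), and that for apoptosis genes without plasmablast replicate 2 or with binding in either library (adjusted p = 0.0637 and 0.0532, Fisher's exact test).

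Over all lists and cell types, 39 of 126 tests passed, 28 above and 11 below the rate of other genes, and 47 had an unadjusted p under 0.05 (Fisher's exact test). Olfactory receptor genes, a reference list, were bound below it in each of the 6 cell types, in 1 to 6 of 1109 cases. Of the 315 tests of a difference between 2 cell types 8 passed, each against plasmablasts. This number was 44 with binding in either library, 25 with a 5 kb window and 16 without d6 PGCLC replicate 2. The number of bound genes was not made equal between cell types, and plasmablasts had by far the most. For B cell genes this test had no room to pass toward plasmablasts: of those bound in exactly 1 of intestinal epithelium and plasmablasts, 0 were in the intestine and 20 in plasmablasts, but so were 196 and 7271 other genes. The olfactory receptor genes gave 4 in d2 PGCLC against 1 in plasmablasts (adjusted p = 0.00304), a call lost with a 500 bp window (adjusted p = 0.0846, Fisher's exact test).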

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

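The tests on d6 PGCLC replicate 1, that of list length and that of the 10 splits for gene ends, and those of list length and of the ratio of the sexes for the X chromosome were chosen after the results they bear on had been seen. The tests on few cells and on X list length replaced earlier ones that rested on a comparison of single libraries and came out the same way.

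Gene lists showed a tested difference between cell types in 8 comparisons, each against plasmablasts, by Fisher's exact test with adjusted p. Photoreceptor genes in photoreceptor precursors gave 1.72e-06, mature intestinal genes in intestinal epithelium 7.18e-05, pluripotency genes 8.46e-05 in d2 PGCLC and 0.00493 in d6 PGCLC, and intestinal transcription factors in intestinal epithelium 0.00118. Olfactory receptor genes in d2 PGCLC gave 0.00304 on 4 genes against 1 (0.0846 with a 500 bp window), retinal progenitor and neurogenic genes in d6 PGCLC 0.0112, and bipolar cell genes in photoreceptor precursors 0.0446. The neurogenic call was lost in 3 of 17 alternatives (highest adjusted p = 0.172, Fisher's exact test), the bipolar call in 1 (0.0909, without photoreceptor precursor replicate 2) and the d2 PGCLC pluripotency call in 1 (0.0504, with a 500 bp window). Many of the 17 could hardly change a call. The merging distance does not enter gene counts, and leaving out a library of a cell type not compared alters only the adjustment. The number of such differences was 44 with binding in either library, 25 with a 5 kb window and 16 without d6 PGCLC replicate 2. Bound genes were not made equal in number, with 8691 in plasmablasts and 1267 to 2128 in the other cell types. A list bound below the rate of other genes in plasmablasts can thus pass without a call above that rate elsewhere. Mature intestinal genes did so, with adjusted p = 0.222 in intestinal epithelium (Fisher's exact test).

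Signals in data outside the main measurement were summits on sequences other than the chromosomes analysed, which totalled 71 on the unplaced sequence JH584304, 71 on other unplaced sequences and 31 on the mitochondrial genome over the 12 libraries.

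The d6 PGCLC replicate 1 list was 4.94 times as long as that of replicate 2. Random placement as the whole source is argued against: of its 65398 summits absent from replicate 2, 20.4% coincided with a d2 PGCLC or E12.5 PGC summit, 14.0 times the 1.46% after 20 kb shifts. Few cells as the whole source is argued against too, since the longest list of the other 3 libraries made from under 4e5 cells reached 0.234 of its length. Deeper sequencing or a looser threshold stays open: the additional summits coincided 0.231 times as often as summits of both replicates, but the latter were picked for being found again, so this decides nothing. A difference between the cultures was not tested.

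Summits lay near gene ends more often in the 3 somatic than in the 3 germ-lineage cell types. List length is argued against, since the lowest somatic library exceeded the highest germ-lineage library by 7.68 percentage points although both sets held short and long lists. Summits not found in both libraries are argued against as well, since in bound regions the gap between the lowest somatic and the highest germ-lineage cell type was 8.44 points. The 10 splits of 6 cell types are too few for a share under 0.05: 1 split was as large as the real difference of 12.53 points, and the highest other gave 6.34. Among restricted regions only plasmablasts (24.0%) exceeded every germ-lineage type, with 9.21% in intestinal epithelium and 6.11% in photoreceptor precursors against 4.04% to 9.68%. Germ-lineage identity, which may be the source, cannot be told apart from the sort, since the somatic cells were sorted for GFP and the germ-lineage cells were not. Cell number was not tested, with 8.8 to 11 in units of 1e5 in somatic and 3.0 to 30 in germ-lineage libraries.

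The female E12.5 PGC library had 1.703 times the X share of the male. List length alone is argued against, since the longer list of a replicate pair exceeded the shorter in X share by at most 1.18 times, in d6 PGCLC with its 4.94-fold difference in length. Summits of the female library alone stay open: among regions with a PGCLC summit the ratio was 1.33 (2.101% against 1.577%), but these regions still include female-only ones, and common regions have 1 X share for both sexes, so this test cannot exclude them, although its bound was set before its value was seen. X copy number or another sex difference may be the source, with 1.72 times as many X summits per other summit, but with 1 library per sex it cannot be told apart from a difference between the libraries.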

How the results depend on the processing

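Alternatives were planned before the data were examined, except thinning, the bound regions for the gene-end share and 1 gene per region. With binding in either library, the median number of bound regions became 26361, restricted regions 116054, regions bound in all cell types 2150, germ-lineage-restricted regions 4943, regions of all 3 stages 10873, bound genes 4096 and list differences 44. With lists thinned at random to the shortest, which by its construction lowers the counts of long lists most, these were 1975.7, 4468.9, 0.1, 4.9, 11.5 and 517.8 (list calls and list differences not run), and regions common to the sexes 2216.1. Gene-end windows of 500 bp and 5 kb gave a median of 1226 and 3639.5 bound genes, a median share of 13.7% and 35.5% and a somatic excess of 10.1 and 14.7 percentage points, 5 kb gave 25 list differences, and all annotated genes gave a share of 24.8%. Leaving out each library gave a median over the 6 cell types of 9582.5 to 11661.5 bound regions (within d6 PGCLC 11311 to 75891), 19772 to 62248 restricted regions (highest without d6 PGCLC replicate 2), 1094 to 1182 in all cell types, 1644 to 2481 germ-lineage-restricted (highest without the male E12.5 library), 4671 to 6108 in all stages, a median of 1979 to 2123 bound genes (within intestinal epithelium 1596 to 3686), 38 to 43 list calls, 7 to 16 list differences (highest without d6 PGCLC replicate 2) and r of -0.17 to 0.30 for cell number, positive without d6 PGCLC replicate 1. Merging at 100 or 500 bp kept region counts within 1.5 times, except that E12.5 PGC had 142 restricted regions in place of 223 at 500 bp, and does not enter gene counts. Of the 39 list calls 9 were lost at 500 bp, 3 at 5 kb and 4 with either library, none changed direction, and the 6 for MHC class I passed under each of the 18 alternatives run for list calls. Many of these 18 could hardly change a given call, since the merging distance and libraries of other cell types leave its gene counts unchanged. Replicate overlap passed under each alternative, the replicate block included (0.319, exact permutation p = 0.0167); same-numbered replicates share only a number. Score-based, motif and CpG alternatives were not run, since the lists hold no score and no genome sequence was used. Apart from thinning and the numbers of libraries, the cause of these changes was not tested, and unknown depth limits every count.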

Other observations

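In a scan of 116 gene families defined by the start of the symbol, chosen after the data were seen, 41 of 49 Nduf genes (subunits of mitochondrial complex I), 39 of 49 Mrpl genes (mitochondrial ribosome), 31 of 35 Vps genes (vesicle sorting) and 24 of 28 Polr genes (RNA polymerase subunits) were bound in plasmablasts, against 39.6% of other genes (Fisher's exact test, two-sided, adjusted p = 1.51e-08, 7.51e-07, 9.86e-08 and 1.81e-05 over 696 tests). The ribosomal reference list had 42 of 46 genes (91.3%) bound in plasmablasts, so an excess of this size was not particular to these families. In d2 PGCLC the 4 families had 5, 0, 2 and 1 genes bound, none past the threshold. Of the 696 tests 92 passed, 44 below and 48 above the rate of other genes, and of the latter 35 were in plasmablasts and 7 in photoreceptor precursors. The 4 families named were chosen after their values were seen. The difference between cell types was not tested for families.

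Bound regions near gene ends and elsewhere were compared for binding in another cell type, without a test. In E12.5 PGC 93.7% of regions near a gene end were bound in another cell type, against 83.6% of the other regions, and in photoreceptor precursors 74.9% against 34.8%. In plasmablasts the values were 27.3% and 24.3%.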
